A study of Mus musculus with 4 samples.

How the data were processed

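ATAC-seq was performed on MPP3 cells from bone marrow of mice aged 3 months, with a commercial library kit (Vazyme Hyperactive ATAC-Seq), per the labels' protocols. The 4 libraries were grouped by their titles into T1 and T2, with 2 libraries each, numbered 1 and 2 in both groups.

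The submitters' processing notes name Bowtie2, SAMtools and MACS2 and the genome build mm10. Versions, settings, read filters, the shift for transposase insertion and any pooling are not given in the sources used here. Peak names carry 1 library prefix per file, so the authors called peaks per library. The deposited fold value of each peak is a ratio of its summit to the local background within its library, in the column order that MACS2 writes. The deposited −log10 p and −log10 q values measure significance against that background, and every −log10 q was at least 2. The deposited score is a whole number, 10 times the −log10 q without its decimals for nearly all peaks. The deposited summit offset gives the summit's distance from the peak start. None of these values is a read count, so no count model was fitted and the values were used only to rank and filter peaks within a list. A longer list may come from deeper sequencing or better signal over background, and the lists cannot tell these apart. Depth per library is therefore unknown, and precision is given only as binomial intervals on counts of regions.

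Peaks on chromosomes 1 to 19, X and Y were kept. No interval was repeated within a list. Peaks that overlapped by at least 1 bp were joined across the 4 lists into regions, and a library had a region where it had a peak in it. Counts of group-only regions were set beside those of the other 2 splits of the libraries, because 2 against 2 libraries allow an exact two-sided p no lower than 0.333. Gene positions came from a RefSeq gene table on GRCm38.p6, the assembly that mm10 names, which gives gene starts and ends without strand or exons. Transcription start sites could not be told from gene 3′ ends. The planned promoter windows were therefore placed at both gene ends, the planned nearest start site became the gene body or the nearest gene within 50 kb (89.4% of regions), and exon and intron shares were not computed. The motif comparison needs a genome sequence, which was not used here, so it was not run. Of 442 symbols in the gene lists 440 matched a protein-coding gene.

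The following were fixed before the data were examined: the 22 gene lists, the main comparisons and most other settings. Settings and tests chosen later are named as such where they are given. The rule for genes named in the text was fixed then too. Written for the nearest start site and applied to the gene assignment above, it took Bcl11a, then per direction the 10 genes with the largest difference between T1-only and T2-only regions, and then up to 4 members per list. Ties went to the higher mean −log10 q of the best region. Predicted gene models were left out of the names, and some genes that the rule selects are not reported here. List members reported at gene ends outside that rule were chosen after their values were seen. The lists covered stem cell, granulocyte-monocyte, lymphoid, B, T and NK, erythroid, megakaryocyte, mast cell, dendritic, mature myeloid, interferon, inflammatory, immediate early, cell cycle, apoptosis, BCL11A partner, RUNX and ETS, metabolic, housekeeping, endothelial, stromal and neural or epithelial genes. Lists, chromosomes and gene-end shares were compared by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 22 lists or 21 chromosomes, and shares carry 95% Wilson intervals. Regions and genes are not replicates, so these tests describe the 4 libraries.

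Alternatives were stricter peaks (−log10 q of at least 5 or 10), presence at a −log10 q of at least 5 with absence of any deposited peak, and lists shortened to the 54045 peaks of the shortest. Others were peaks covering at least 0.5 of a region, regions of 250 bp either side of summits, other gene distances (10 and 200 kb) and windows, and leaving out each library. The replicate numbers were not taken to pair the libraries, because the labels tie them to no shared animal, batch or day.

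The procedure was tested on simulated lists of 58454 regions in which 200 T1-only and 400 T2-only regions were planted and 5% of regions, planted ones included, were dropped at random from each list. Of the planted regions 181 and 364 were recovered (90.8%, against 90.25% expected from the losses), and 279 others were called against 261 expected. The losses were assumed, so these values test the code and not the sensitivity of the real lists. The list test was run on 1000 simulated lists of each of 4 sizes, with a T1-only share of 60% against 25% elsewhere. At the level that a single list of 22 needs after adjustment it called 0% of lists of 4 regions, 18.8% of 10, 48.0% of 17 and 81.7% of 28, and it called 1.7% to 4.7% of unshifted lists at an unadjusted p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.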

Results

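Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in 4 libraries of MPP3 cells sorted from mouse bone marrow. MPP3 cells are a multipotent haematopoietic progenitor population with a bias towards granulocytes and monocytes. The animals were WT-iMOS mice 3 months of age, and the libraries fell into a T1 group of 2 and a T2 group of 2. The labels do not say what T1 and T2 stand for, nor whether replicates came from separate animals. Peak names carry the prefix WG in the T1 lists and MG in the T2 lists, which no label explains, and the naming of the lists leaves open whether the 2 replicates of a group are separate biological samples. The spread between replicates may therefore be technical only. The series asks how Bcl11a, a zinc-finger transcription factor, acts within MPP3 cells, and the comparison its design implies is T1 against T2. Each library is represented by the authors' own list of accessible sites (peaks) on mouse genome build mm10. Sequencing depth is unknown, because the peak lists carry no read counts. The T1 lists held 58469 and 54057 peaks (replicates 1 and 2) and the T2 lists held 66776 and 62718, that is 56263 ± 3120 against 64747 ± 2869 peaks (SD, n = 2 per group). The peaks covered 32.8 ± 3.29 Mb in T1 and 37.4 ± 2.98 Mb in T2 (SD, n = 2 per group).

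Overlapping peaks of the 4 lists were joined into 77914 regions. A region is called T1-only below where both T1 libraries and neither T2 library had a peak, and T2-only in the opposite case. Peak strength is given as the authors' −log10 q, the peak's own significance over local background within its library. It ranks peaks within a list and is not compared between lists. A region is described as near a gene when it lies in the gene body or when that protein-coding gene is the nearest within 50 kb.

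The Bcl11a locus was accessible in both groups, with 4 T2-only regions and 1 T1-only region, where T2-only regions outnumbered T1-only ones 2.96 times over the whole genome. The gene spans 24076564 to 24173558 on chromosome 11, and the gene with 50 kb on either side held 23 regions. Peaks were present at 18 and 15 of these in T1 replicates 1 and 2 and at 20 and 19 in T2 replicates 1 and 2. All 4 libraries shared 13 regions, 4 were T2-only, 1 was T1-only and 5 had other combinations. The strongest T2-only region lay inside the gene, at 24136167 to 24136507, with −log10 q of 14.2 and 7.64 in the T2 replicates. The others were at 24094090 to 24094461 inside the gene, and at 24060920 to 24061304 and 24214807 to 24215106 outside it. The T1-only region, at 24163986 to 24164999 inside the gene, was weak, with −log10 q of 3.60 and 3.05, and at 1014 bp wider than the 4 T2-only regions (300 to 385 bp). Exon positions were not used here, so whether it lies on an exon is open. With peaks of −log10 q of at least 5 in every list, 2 T2-only and 0 T1-only regions were left. With the lists shortened to equal length, 1 T2-only and 0 T1-only regions were left. T1-only regions numbered 2 without T1 replicate 2 or without T2 replicate 2, and T2-only regions numbered 5 without T1 replicate 1 or without T2 replicate 2. No test across libraries was made, since 2 libraries against 2 cannot give an exact two-sided p below 0.333.

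**Figure D1:**
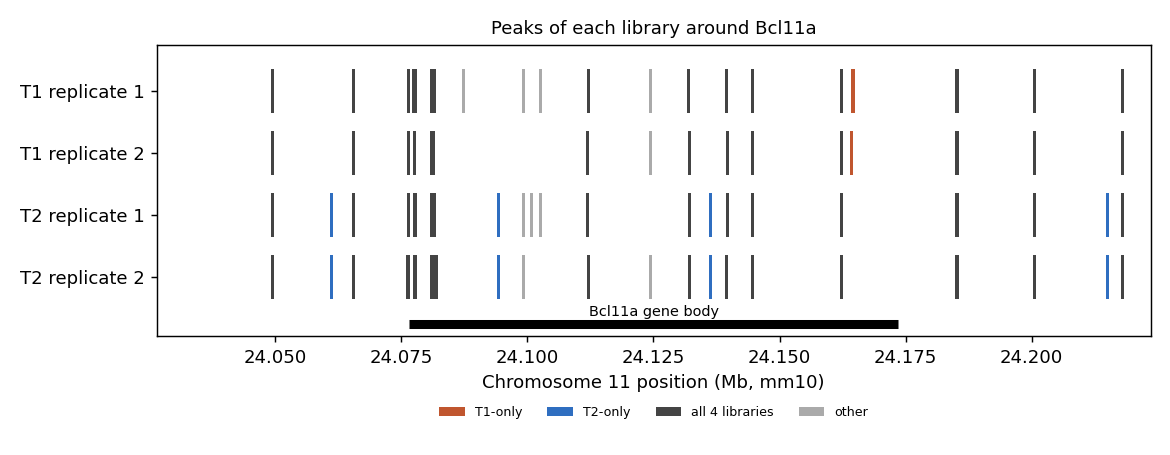
Peaks of each library over Bcl11a and 50 kb on either side (x axis, position on chromosome 11 in Mb, mm10; y axis, the 4 libraries). Each bar is 1 peak, with narrow peaks widened to be visible, and is coloured by the class of its region: 13 regions are shared by all 4 libraries, 4 are T2-only and 1 is T1-only.

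Between T1 and T2, most regions found in both libraries of a group were shared, and those that were not lay mainly away from gene ends. With the lists as deposited, the largest excess of T2-only over T1-only regions was near Grik4, a kainate-type glutamate receptor subunit, with 6 T2-only and 0 T1-only among 27 regions. Pde4d, a cAMP phosphodiesterase, had 6 and 1 among 60, Chst11, a chondroitin sulfotransferase, had 5 and 0 among 32, and Ablim1, an actin-binding LIM protein, had 6 and 1 among 31. Rarb, the retinoic acid receptor beta, had 5 T2-only and 0 T1-only among 18 regions, and 1 of these T2-only regions, at 17081972 to 17082223 on chromosome 14 with −log10 q of 12.7 and 13.5, lay at a gene end. Ano1 (5 and 0 among 15), Carmil1 (5 and 1 among 14), Farp1 (4 and 0 among 13) and Megf11 (4 and 0 among 16) were also on the T2 side. The order depends on the peaks used. With −log10 q of at least 5, with at least 10 and at equal list length the excess was 3, 2 and 2 at Grik4. It was 6, 6 and 4 at Pde4d and 6, 5 and 5 at Ablim1, and it was 0 at Ano1 with at least 10. In the same settings the excess was 4, 3 and 2 at Chst11, 3, 4 and 3 at Rarb and 2, 3 and 1 at Carmil1. At Farp1 it was 4, 3 and 3, and at Megf11 it was 4, 1 and 2.

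On the T1 side, Thada had 4 T1-only and 0 T2-only among 18 regions and Stxbp6, a SNARE-binding protein, had 4 and 0 among 9. The strongest of the Stxbp6 regions lay inside the gene at 44932973 to 44933527 on chromosome 12, with −log10 q of 29.2 and 17.2 in the T1 replicates. Mcf2l, a guanine nucleotide exchange factor, had 3 and 0 among 12, and its strongest T1-only region (chromosome 8, 12983864 to 12984505) had −log10 q of 65.7 and 51.4 in T1 with no deposited peak in either T2 library. Fndc3b (4 T1-only and 1 T2-only among 18), Rasgrf1 (4 and 1 among 15), Gda (4 and 1 among 9), Rin2 (3 and 0 among 18), Plbd1 (3 and 0 among 7), Atp2b2 (3 and 0 among 14) and Ankrd55 (3 and 0 among 15) followed. All 10 of these genes kept an excess of T1-only regions under 6 other ways of defining peaks and regions, but its size changed. With −log10 q of at least 10, T2-only minus T1-only regions came to −1 at Fndc3b and at Atp2b2, against −3 with the lists as deposited. Equal list length, 1 of these settings, raised T1-only regions over the genome from 1814 to 3143, so it favours an excess on this side. Genes with many regions have more chances to hold group-only ones, so these counts rank genes and do not test them.

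In total, 44274 regions (56.8%, 95% Wilson interval 56.5 to 57.2) had a peak in all 4 libraries, 5364 (6.88%, 6.71 to 7.06) were T2-only and 1814 (2.33%, 2.22 to 2.44) were T1-only. Intervals here and below cover counting error only. Of the regions found in both libraries of a group, 9.56% (9.32 to 9.81) were T2-only among 56094 in T2 and 3.75% (3.58 to 3.92) were T1-only among 48372 in T1. Group-only regions were weaker and narrower than shared ones. In T2 replicate 1, T2-only peaks had a median −log10 q of 10.9 and a median width of 321 bp, against 39.2 and 635 bp for peaks in shared regions. In T1 replicate 1, the values were 11.1 and 355 bp for T1-only peaks and 32.8 and 606 bp for shared ones.

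Parting the 4 libraries in the other 2 ways gave fewer regions of this kind. The T1 and T2 split gave 7178 in all, parting by replicate number gave 1941, and the remaining split gave 1616. Libraries of the same group overlapped more than libraries of different groups. The base-pair Jaccard index was 70.1% for the T1 pair and 71.5% for the T2 pair, and between 63.5% and 67.6% for the 4 pairs across groups. The mean within groups was 4.81 percentage points above the mean between groups, the largest of the 3 splits, for which the exact permutation test gives p = 0.333, the smallest it allows. The numbers of T1-only and T2-only regions moved with the length of the lists. When each list was shortened to its 54045 strongest peaks, 3143 regions were T1-only and 2957 T2-only, so the excess of T2-only regions was lost (ratio 0.941 against 2.96). Lists of equal length leave similar numbers of unmatched peaks on both sides, so this setting brings the ratio near 1 by construction. When 1 library was left out, its partner alone decided for the group, and T1-only regions numbered 4694 without T1 replicate 2, 3398 without T1 replicate 1 and 3387 without T2 replicate 1, and T2-only regions 11704 without T2 replicate 2, 9851 without T1 replicate 1 and 9032 without T2 replicate 1.

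**Figure D2:**
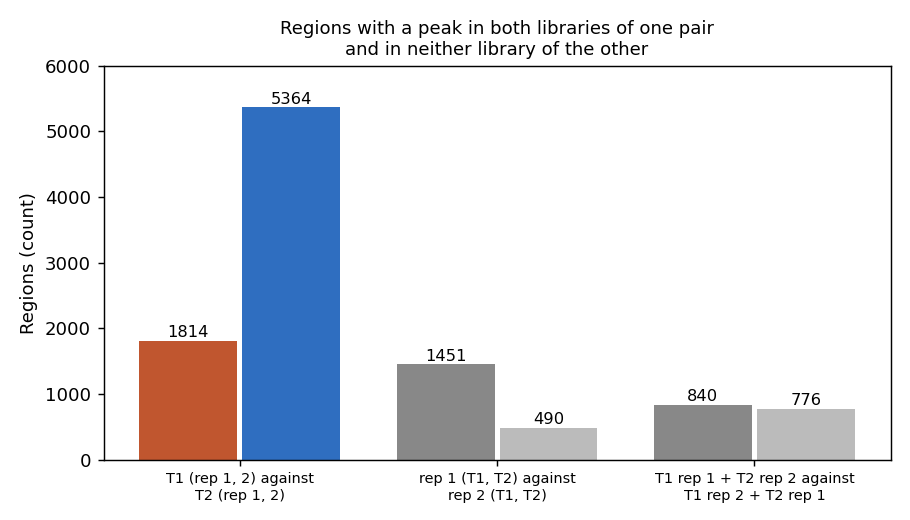
Number of regions (y axis, starting at 0) with a peak in both libraries of one pair and in neither library of the other, for the 3 ways of parting the 4 libraries into pairs. The T1 and T2 split gives 1814 T1-only and 5364 T2-only regions, and no other bar exceeds 1451.

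Near genes of blood cell programmes, T2-only regions outnumbered T1-only ones for most lists, as they did across the genome. The 28 genes of the stem cell and multipotency list had 15 T2-only and 2 T1-only regions among 259, with more T2-only than T1-only regions at 8 genes and the opposite at 0. Mecom, a transcription factor required for stem cell maintenance, had 4 T2-only and 0 T1-only regions, and the strongest, at 29991673 to 29991941 on chromosome 3, had −log10 q of 10.6 and 12.3. Vwf, which encodes von Willebrand factor, had 3 and 0, and Cdkn1c and Hlf had 1 and 0 each. The 25 genes of the granulocyte-monocyte list had 10 T2-only and 5 T1-only regions. Irf8, a transcription factor of the monocyte and dendritic lineages, and Hdc, histidine decarboxylase, had 3 T2-only and 1 T1-only each. Csf3r, the G-CSF receptor, and Ly6c2, a monocyte surface protein, had 1 T1-only and 0 T2-only each. The Ly6c2 value is uncertain, because the Ly6 family holds near-identical copies whose reads can be shared. The mature neutrophil and macrophage list was the one list of the 22 with more T1-only than T2-only regions, 3 against 1. S100a8 and S100a9, the subunits of calprotectin, had 1 T1-only region each, at 90668851 to 90669280 (−log10 q of 14.5 and 14.7) and at 90686726 to 90687162 (15.5 and 13.2) on chromosome 3. Cxcr2 also had 1 T1-only region, a difference that reversed with peaks of −log10 q of at least 10 and without T1 replicate 2, and Retnlg had 1 T2-only region. At equal list length the T2-only excess was 1 at Mecom and 0 at Vwf, Cdkn1c, Irf8 and Hdc, and with peaks of −log10 q of at least 10 it was 0 at Hlf, Irf8 and Hdc.

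Lists of the other lineages held few group-only regions each. The lymphoid priming list had 10 T2-only and 2 T1-only regions, with 2 T2-only and 0 T1-only at Ikzf1, Ccr7 and Runx2 and 1 and 0 at Sox4. The B lineage list had 7 and 2, with 1 T2-only region each at Ebf1, Ciita, Pou2af1 and Cd79b. The T and NK list had 6 and 4, with 1 T2-only region at Id2 and at Tbx21, and 1 of each class at Ets1 and Thy1. The erythroid list had 11 T2-only and 4 T1-only regions. Ank1, an erythrocyte membrane ankyrin, had 2 and 0, Zfpm1 had 2 and 1, and Aqp1 and Car1 had 1 and 0, the Car1 region lying at a gene end (chromosome 3, 14808284 to 14808681, −log10 q of 32.0 and 5.97). The megakaryocyte list had 8 and 2, with 2 and 0 at Fli1 and Gp1bb and 1 and 0 at Pf4, the platelet factor 4 gene. The 2 Gp1bb regions lay side by side on chromosome 16, at 18620827 to 18621237 and 18621431 to 18621879, so they may not be separate sites. The mast cell, basophil and eosinophil list had 7 and 3, with 1 T2-only region at Il5ra and Ccr3 and 1 of each class at Mitf. The 3 T2-only regions and 1 T1-only region of Hdc, given above under the granulocyte-monocyte list, count here too. The dendritic cell list had 5 and 1, with 2 T2-only regions at Tcf4, 1 at Zbtb46 and 1 T1-only region at Xcr1. The T2-only region of Id2, given above under the T and NK list, counts here too. At equal list length the direction reversed at Runx2, Fli1 and Tcf4, and at Runx2 also with peaks of −log10 q of at least 10. The difference was 0 at equal list length at Ccr7, Ciita, Pou2af1, Cd79b, Tbx21, Car1, Gp1bb, Il5ra and Ccr3. It was also 0 at Sox4, Aqp1 and Zbtb46 with −log10 q of at least 10, at Id2 with windows around summits, and at Xcr1 with peaks that cover at least 0.5 of a region.

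The list of BCL11A partners and globin regulators had 15 T2-only and 6 T1-only regions. Bcl11a is itself a member, and its 4 and 1 regions described above are counted there. The other members had 11 T2-only and 5 T1-only regions, with 2 and 0 at Nfix and Rcor1 and 1 and 0 at Zbtb7a. The 2 Rcor1 regions lay close together on chromosome 12, at 111028473 to 111028820 and 111029352 to 111029697, so they may not be separate sites. The list of RUNX, ETS and other regulators had 18 and 10. Runx1, a regulator of definitive haematopoiesis, had 5 T2-only and 3 T1-only regions, a difference that reversed at equal list length and with peaks of −log10 q of at least 10, and Tet2 and Ikzf2 had 2 and 0. The 2 T2-only regions of Fli1, given above under the megakaryocyte list, count here too. Cell cycle genes had 12 and 4, with 2 and 0 at Cdkn1a, Ccnd2 and Cdkn2a and 1 and 0 at E2f2. Apoptosis genes had 4 and 2, with 1 T1-only region at Pmaip1, 1 T2-only at Bcl2l11 and 1 of each class at Bcl2. The 2 T2-only regions of Cdkn1a, given under the cell cycle genes, count here too. Inflammatory genes had 9 and 5, with 2 T2-only regions at Socs3 and Nfkb1, 1 at Il6ra and 1 T1-only region at Tlr2. The direction at Nfkb1 reversed without T1 replicate 2. Immediate early genes had 7 and 1, with 1 T2-only region at Fosb, Fos, Klf2 and Ier3. The direction at Fos reversed at equal list length and with peaks of −log10 q of at least 10. Interferon response genes had 2 and 1, with 1 T2-only region at Oasl1 and Ifih1 and 1 T1-only region at Usp18. Metabolic genes had 9 and 0, with 2 T2-only regions at Ppargc1a and 1 at Slc2a1, Pdk4 and Eno1. Housekeeping genes had 3 and 0, with 1 T2-only region at Polr2a and at Ywhaz. Of lists for cells the sort should leave out, endothelial genes had 3 T2-only and 1 T1-only regions, with 1 T2-only region at Flt4 and Sox18 and 1 of each class at Cdh5. Stromal genes had 6 and 1, with 1 T2-only region at Col1a2 and Ebf3 and 1 T1-only region at Cxcl12. The 2 T2-only regions of Runx2, given above under lymphoid priming, count here too. Neural and epithelial genes had 9 and 1, with 3 T2-only regions at Neurod1, 1 at Myod1 and Rbfox3 and 1 T1-only region at Cdh1, where the direction reversed without either T2 replicate. Among the genes of this paragraph, the difference was 0 at equal list length at Nfix, Rcor1, Tet2, Cdkn2a, Bcl2l11, Klf2, Ier3, Ifih1, Ywhaz, Col1a2, Ebf3 and Rbfox3. It was also 0 at Ikzf2, Ccnd2, Nfkb1, Usp18, Slc2a1 and Cxcl12 with −log10 q of at least 10, and at Pmaip1 and Cdh1 with peaks that cover at least 0.5 of a region. The T2-only region of Slc2a1 had −log10 q of 45.8 and 47.0, above that cut, so the 0 there was not its loss. A difference of 0 can thus come from a newly counted region of the opposite class.

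None of the 22 lists was found to have a T1:T2 split different from the split near other genes, where 25.3% of group-only regions were T1-only. By Fisher's exact test (two-sided), 0 lists passed an adjusted p of 0.05 and 0 had an unadjusted p under 0.05. The lowest unadjusted p, 0.0527, was that of the mature neutrophil and macrophage list, at 75.0% T1-only (95% Wilson interval 30.1 to 95.4, 4 regions). For the stem cell list the share was 11.8% (3.29 to 34.3). In other settings 0 lists passed too, but up to 3 had an unadjusted p under 0.05, the 3 with −log10 q of at least 10. Lists were also compared by the T2-only share of regions found in both libraries of at least 1 group. The erythroid list stood at 16.4% against 8.53% elsewhere. It alone had an unadjusted p under 0.05 there, and 0 lists passed after adjustment. Regions are not replicates, and the lists held 3 to 28 group-only regions each. In simulated lists with a T1-only share of 60%, the test with adjustment called 0% of lists of 4 regions and 18.8% of lists of 10, so a shift of that size could go unseen in most lists. Shifts towards T2-only were not simulated. The metabolic list, with 9 T2-only and 0 T1-only regions, had an unadjusted Fisher's exact p of 0.123 (two-sided). A list of that size therefore could not pass in that direction.

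**Figure D3:**
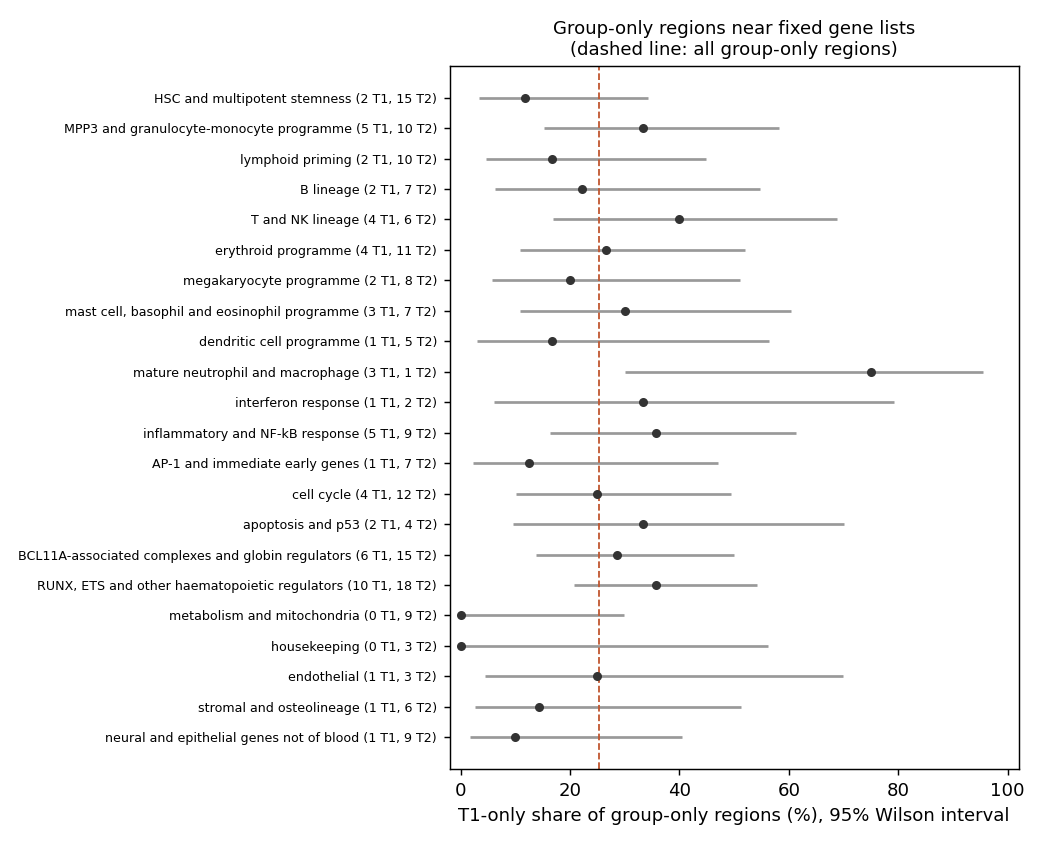
Share of group-only regions that were T1-only (x axis, percent) near each of the 22 gene lists (y axis, with the counts of T1-only and T2-only regions), with 95% Wilson intervals. The dashed line marks 25.3%, the share over all group-only regions, and the mature neutrophil and macrophage list is the only one above 50%, on 4 regions.

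Gene ends were largely alike in the groups. They include a promoter only where its start site lies at an annotated end of the gene, so start sites further inside a gene were not covered. Of 21887 protein-coding genes, 13060 had a peak within 1 kb of an annotated end in all 4 libraries, 255 had one in both T2 libraries and neither T1 library, and 35 in both T1 and neither T2. Among housekeeping genes 17 of 18 had a gene-end peak in all 4 libraries, against 20 of 21 immediate early genes, 24 of 27 cell cycle genes, 23 of 28 stem cell genes, 18 of 25 granulocyte-monocyte genes, 7 of 20 mature neutrophil and macrophage genes, 5 of 18 B lineage genes and 8 of 20 neural and epithelial genes. T1-only gene ends in the fixed lists were at Ly6c2, S100a8, Mrc1, the mannose receptor of macrophages, and Mpig6b, a platelet receptor. T2-only gene ends were at Mpo, the neutrophil myeloperoxidase, at Car1, Il5ra, Gp1bb and Clec1b, and at the neural and muscle regulators Neurod1, Olig2 and Myog. Mrc1, Mpig6b, Mpo, Clec1b, Olig2 and Myog are named because they were the remaining list members, after their values were seen. The ends of Neurod1, Olig2 and Myog were no longer T2-only with −log10 q of at least 5 or at equal list length, nor those of Car1, Gp1bb and Il5ra with at least 10 or at equal list length. The end of Mrc1 was no longer T1-only with −log10 q of at least 10, nor that of Mpig6b with windows around summits. At equal list length the counts were 121 T2-only and 128 T1-only gene ends. Leaving out 1 library gave 66 to 108 T1-only gene ends (66 without T2 replicate 2, 73 and 97 without T1 replicates 1 and 2, 108 without T2 replicate 1), and 524 and 451 T2-only ones without T1 replicate 1 and T2 replicate 2.

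By location, 26.9% (95% Wilson interval 26.4 to 27.3) of shared regions had their midpoint within 1 kb of a gene end, against 7.64% (6.96 to 8.39) of T2-only and 3.75% (2.97 to 4.73) of T1-only regions. Gene bodies further from the ends held 52.4% of T1-only, 49.0% of T2-only and 40.6% of shared regions. The share at gene ends in T1-only minus that in T2-only regions was −3.89 percentage points (Fisher's exact test, two-sided, p = 1.61e-09). This difference was not kept with regions built from 250 bp on either side of the summits (−1.12 points, exact p = 0.116) or at equal list length (0.216 points, exact p = 0.758). It was −2.11 points without T2 replicate 1 and −2.11 without T2 replicate 2. Fisher's test treats regions as independent, while regions of a class clustered along chromosomes, as given below, so these p-values may be too small.

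The T1-only share of group-only regions was similar across chromosomes, from 21.4% on chromosome 4 to 29.1% on chromosome 8 among chromosomes other than Y, with 25.3% overall. Chromosome Y held 4 T2-only and 0 T1-only regions, with 7 and 7 peaks in T1 replicates 1 and 2 and 12 and 10 in T2 replicates 1 and 2. The sex of the animals was not taken into account for chromosomes X and Y. No chromosome differed from the others by Fisher's exact test (0 of 21 at an adjusted p of 0.05, 1 at an unadjusted p under 0.05, lowest adjusted p 0.634). At equal list length chromosome X stood apart, with 67 T1-only and 33 T2-only regions (exact test, adjusted p = 0.0362). Without T1 replicate 2, chromosome 4 did, with 261 and 519 (exact test, adjusted p = 0.0297).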

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

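The tests of random losses and of libraries made together were chosen after the results were seen, and the test of weak T2-only peaks before. Peaks on unplaced or unlocalised scaffolds were left out of the comparisons and are given here because they lie outside the data compared. They numbered 15 and 12 in T1 replicates 1 and 2 and 12 and 14 in T2 replicates 1 and 2, each above the 3 that a count of 0 allows, a low bound that says nothing of the groups.

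T2-only regions outnumbered T1-only regions by 5364 to 1814. A candidate explanation is that weak peaks fell below the threshold in the shorter T1 lists. It predicts that few T2-only regions are strong, and 4.01% (95% Wilson interval 3.52 to 4.57) lay above the median −log10 q of both T2 lists. This is under a bound of 5% that was set beforehand without a model behind it. The ratio of T2-only to T1-only regions did not shrink with stricter peaks. It was 3.24 with −log10 q of at least 5 in every list and 3.60 with at least 10, against 2.96 as deposited. It was 3.07 where presence needed at least 5 and absence meant no deposited peak. The T2 lists stayed the longer ones at both cuts, so peaks just under a new threshold could still be missed in T1. Missed weak peaks therefore stay open as a source of the excess. The 215 strong T2-only regions are a larger share than the 0.902% to 1.52% found for regions held by exactly 2 libraries of different groups, and for T1-only regions the share was 6.45% (5.41 to 7.67). A biological difference between T1 and T2 cells stays open and was not tested apart from this.

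Each group held regions that the other lacked. Random losses of weak peaks may leave such regions in any pair of libraries, but T1-only regions exceeded the largest count for a pair across groups (1451) by 363, although the T1 lists were the shorter ones, which argues against random losses as the whole source. Libraries of a group made or sequenced together could give the same overlap, 4.81 percentage points higher within than between groups. The labels give no batch, day or animal, so this cannot be told apart from a difference between T1 and T2. With 3 splits of the libraries no share under 0.05 can be had, and the real split gave 7178 regions against 1941 for the highest of the others.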

How the results depend on the processing

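The alternatives without chromosome Y and with the nearest gene end and the differences by replicate number were added after seeing the data; the others were planned. For the region classes, no paired analysis was possible because they come from no fitted model to which a replicate block could be added, and a T2-only region already has its peak in the T2 and not in the T1 library of both numbers. Across groups the Jaccard index was 67.3% and 65.5% for libraries of the same number and 67.6% and 63.5% for the others, and T2 lists were longer by 8307 and 8661 peaks for the same number and by 4249 and 12719 for different numbers, so with 2 pairs pairing stays open. The motif comparison with its alternatives and the exon and intron shares were not run. With lists of equal length, T1-only regions numbered 3143 and T2-only 2957 (ratio 0.941), gene ends 128 T1-only and 121 T2-only, the gene-end share differed by 0.216 points, 1 chromosome passed, and the Bcl11a locus had 1 T2-only region more than T1-only, as it also had with −log10 q of at least 10 (1, against 3). With at least 10 that region was 24162084 to 24162481, which had a deposited peak in all 4 libraries. Its −log10 q was 8.97 and 6.54 in T1 and 12.1 and 16.4 in T2. Shortening the lists removes mainly weak T2 peaks, and 86.2% of T1-only but 49.7% of T2-only regions were called again. With −log10 q of at least 10, 688 T1-only (37.9%) and 1976 T2-only regions (36.8%) were called again. That setting counted 1336 T1-only and 4811 T2-only regions, so many of these had another class with the lists as deposited. The gene-end share was −1.12 points with summit windows and −2.11 without either T2 replicate. Leaving out 1 library relaxes the definition by construction and gave 2564 to 4694 T1-only and 7396 to 11704 T2-only regions (T1-only 4694, 3398 and 3387 without T1 replicates 2 and 1 and T2 replicate 1; T2-only 11704, 9851 and 9032 without T2 replicate 2, T1 replicate 1 and T2 replicate 1), a ratio of 1.58 without T1 replicate 2 to 4.56 without T2 replicate 2, 66 to 108 T1-only gene ends (66 without T2 replicate 2, 108 without T2 replicate 1) and 367 to 524 T2-only ones (524 and 451 without T1 replicate 1 and T2 replicate 2), and 0 to 1 chromosomes (1 without T1 replicate 2). In the other planned settings, including those that leave out a library, the ratio stayed above 1. No list passed in any setting, with lowest adjusted p from 0.0801 without T2 replicate 2 to 1. The difference in T2-only minus T1-only regions reversed at equal length for Fli1 (−1), Fos (−2), Runx1 (−2), Runx2 (−2) and Tcf4 (−2), with −log10 q of at least 10 for Cxcr2 (1), Fos (−1), Runx1 (−1) and Runx2 (−1), and on leaving out a library for Cxcr2 (−1 to 1), Nfkb1 (−1 to 6) and Cdh1 (−1 to 1). Of 99 genes selected for naming other than Bcl11a, 45 kept their sign in all 6 settings that keep every library. Bcl2, Cdh5, Ets1, Mitf and Thy1, with a difference of 0 and so no sign to keep, are counted among the rest. Depth, which the lists do not give, limits what a missing peak means.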

Other observations

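The tests of myeloid gene ends and of the share per gene, and the listing of the strongest regions, were chosen after the results were seen, and the test of T2-only neighbours before. The strongest group-only regions were absent as peaks from the other group although they ranked above the median of their own lists. The top T1-only region, on chromosome 13 at 44564683 to 44565428, lay over 50 kb from any protein-coding gene and had −log10 q of 70.5 and 68.5. Others lay inside Pde7b, a cAMP phosphodiesterase (56.5 and 45.8), Pdpn, which encodes podoplanin (49.8 and 42.1), and Smyd3 (49.4 and 38.7), and outside genes nearest to Rbpj, the transcription factor of Notch signalling (36.0 and 55.0). The top T2-only region lay inside Lipa, lysosomal acid lipase, on chromosome 19 at 34500737 to 34501077, with −log10 q of 64.8 and 62.5. Others lay inside Wnt5b (56.8 and 47.2) and Herc6 (56.9 and 46.1) and outside genes nearest to Slc2a1, the glucose transporter (45.8 and 47.0).

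A hypothesis set before its result was seen is that group-only regions cluster along chromosomes rather than fall at random among their neighbours. Among neighbouring regions found in both libraries of at least 1 group, 550 pairs were T2-only next to T2-only, against 481 on average in 10000 shuffles of the classes within chromosomes (95% range 444 to 521, permutation p = 0.0008, two-sided) and 487 in shuffles within chromosome and gene-end class (449 to 527, permutation p = 0.0028), which argues against random order. T1-only pairs numbered 94, against 55.9 in the latter shuffles (42 to 70, permutation p = 0.0002, the smallest they can give two-sided), and mixed pairs 273, against 329 (297 to 363, permutation p = 0.001). Weak shared accessibility over a domain, or sensitivity that varies along chromosomes, were not separated. Among 3565 genes with at least 5 such regions, Stxbp6 alone passed a binomial test for T1-only regions (4 of 6, adjusted p = 0.042), 90 had an unadjusted p under 0.05, and 0 passed for T2-only regions (71 unadjusted). This test treats the regions of a gene as independent, which the counts of neighbouring pairs argue against, so its p is too small and the call for Stxbp6 is not secure.

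A further hypothesis is that T1 cells have more open gene ends at myeloid genes. It was examined only for members of the granulocyte-monocyte and mature myeloid lists. Myeloid genes outside them were not counted in either class. Of 35 T1-only gene ends 3 belonged to the granulocyte-monocyte and mature myeloid lists together (Ly6c2, S100a8 and Mrc1), against 1 of 255 T2-only gene ends (Mpo), with a Fisher's exact p of 0.00596 (two-sided). The lists were put together because these genes had been seen, and p was 0.05 or more in 4 of 11 settings (0.0522 with −log10 q of at least 10, 0.0641 without T1 replicate 2, 0.189 without T2 replicate 1), so chance stays open. At equal list length the same 3 and 1 genes stood among 128 and 121 gene ends (exact p = 0.623). That setting brings the totals near each other by construction, so it cannot tell whether the unequal lists account for the contrast. Mature myeloid cells in the T1 sort could also add such peaks. Of 20 mature neutrophil and macrophage genes, 4 had a T1-only region or gene end (Cxcr2, Mrc1, S100a8 and S100a9). A gene-end peak in all 4 libraries was present at 7, and these numbers are too few to decide. The purity of the sort was not examined.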
